A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

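RNA from 1 strain of budding yeast (Saccharomyces cerevisiae, A14201) was measured on 24 two-channel Agilent expression arrays covering 22 labelled time points after release from an Ndt80 block. Per the labels, cells spent 6 hours in sporulation medium and then received 1 µM beta-estradiol, which induces NDT80, the transcription factor needed to leave the pachytene stage of meiotic prophase. Total RNA was extracted with a commercial yeast kit and labelled by an amplification protocol for 2 colours, per the labels. The Cy3 channel of every array held the RNA of a time point and the Cy5 channel held RNA of the same strain in the block, so no dye was swapped. Each ratio is given here as log2 of time point over block. A positive value therefore means more RNA than in the block.

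The deposited scanner output holds spot intensity values for both channels on a linear scale, written by Agilent Feature Extraction 9.5.3.1 with protocol GE2-v5_95_Feb07, per the file headers, and by version 9.501 per the submitters' processing notes. The scanner output also holds a log10 ratio of Cy5 over Cy3 after Feature Extraction's own background and dye steps, per the file headers. A deposited value table of the whole series holds log2 ratios that the authors processed, for 6228 probes. Set against the scanner values it ran as Cy3 over Cy5 on each of the 21 columns with values, with r across probes from 0.968 at 20 minutes to 0.987 at 164 minutes. Its column medians lay between -0.0287 at 140 minutes and 0.0331 at 60 minutes, its column for 100 minutes was empty, and how it was normalized is not given in the sources used here. The table served only as an alternative, and 0 of its columns lacked a sample.

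Each array carried 43792 spots, of which 6256 experimental probes were printed in 7 copies each. The probes carried 6228 systematic names. Of the probes, 5766 matched a locus tag of the supplied RefSeq gene table, which gave the gene symbols, and 490 did not and kept the name in the files. Probe coordinates are those of the files, on the sacCer1 build (SGD, Oct2003), per the file headers. No genome or annotation of that build was used here, so the position of a probe within its transcript is not stated.

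Background was corrected with limma 3.58.1 (normexp, offset 50, mean signal and median local background), and each array was normalized by loess with control spots at weight 0. Control spots and spots flagged as outliers were left out, and the copies of a probe were averaged. For 27 genes with more than 1 probe, the probe with the highest mean brightness represented the gene. A probe was tested when it was well above background in either channel on at least 3 arrays, which kept 6145 probes and 6118 genes. Loess assumes that most genes at each brightness do not change, so a shift shared by most genes cannot be seen, and changes are relative to the median gene. The medians of all tested genes were 0.02, 0.05, -0.02 and -0.11 on the log2 scale in the 4 comparisons below, in the order given.

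The submitters marked the 100-minute array as failing quality control, and it entered no comparison. The second arrays at 132 and 172 minutes were averaged with the first, so that 21 time points had 1 value each. Before the data were examined, the labelled times were divided into 6 windows: 20 to 60, 68 to 92, 100 to 124, 132 to 156, 164 to 190 and 200 to 240 minutes, with 3, 4, 3, 4, 4 and 3 usable time points. A limma model with the window means and 15 residual degrees of freedom tested 20 to 60 minutes against the block (the ratio against 0), 68 to 92 against 20 to 60, 132 to 156 against 68 to 92, and 200 to 240 against 132 to 156 minutes. The block RNA was hybridised only as the reference, so the first test leaves out the block's own spread and keeps any dye bias. A natural spline of time with 4 degrees of freedom (16 residual) tested change over the whole course. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 with a log2 difference, or fitted range, of at least 1. Time points of a window are not replicates: change within a window counts as spread, and nothing in the labels says that the arrays came from separate cultures.

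In the text, NDT80 came first. For each comparison, the named genes were the 12 largest rises and the 12 largest falls among genes that passed, did not overlap between windows, were well above background on the brighter side and had a standard symbol. They also included up to 4 members of each fixed list with the largest change, and the 10 largest fitted ranges of the time course. The text gives a part of these genes, and 1 gene is left out of the named genes and not reported here. The 20 lists (NDT80 itself aside) were fixed before the data were examined and tested with limma's fry, which asks whether the members of a list move, on balance, in 1 direction, with adjustment over 80 tests. Camera, which compares a list with all other genes, served as the alternative with an estimated correlation and with the preset correlation. With the estimated correlation, no list passed in any of the 4 comparisons, and that adjusted p stands beside each list that passed with fry. Some lists share genes, so shifts of such lists are not separate results. The recombination and monopolin lists share REC8, MAM1 and SPO13, and the M-phase and mitotic exit lists share genes such as CDC5 and CDC14. CDC20 and AMA1 are in both the M-phase and the anaphase-promoting complex list, and SWI5 in the mitotic exit and the mitotic G1 list. Ribosomal protein and histone genes have near-identical copies whose probes may take up each other's RNA, and their values are uncertain to that extent.

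The procedure was tested on simulated data for 6118 genes, with noise independent between arrays and so without a slide effect. A call there meant an adjusted p under 0.05 alone. The fold minimum was not applied, so the shares below are upper limits for genes past both thresholds. For 68 to 92 against 20 to 60 minutes, 74.63% of genes changed by a log2 of 1 were called, 97.01% at 2 and 100% at 3, with 8 false calls. For 132 to 156 against 68 to 92 minutes the shares were 61.19%, 97.01% and 100% with 12 false calls, and for 200 to 240 against 132 to 156 minutes 70.15%, 94.03% and 100% with 6. Against the block they were 82.09%, 97.01% and 100% with 5 false calls, and for the spline 47.76%, 92.54% and 100% with 8.

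Alternatives fixed beforehand changed the background correction, the normalization, the source of the values, the filter on dim probes, the treatment of the 100-minute and repeat arrays, the probe per gene, the variance prior, the fold minimum, the spline, the set of time points fitted, the model of time and the set test. They also put the slide (6 slides of 4 arrays, all scanned in 1 batch) into the model as a fixed or a random block, and left out each time point in turn. Leaving out 140, 148 and 156 minutes together, leaving out 84 minutes with both repeat arrays, and using 164 to 190 minutes in place of 132 to 156 minutes were added after the data had been seen. The number of arrays limits the precision. Calculations used R 4.3.3 with the packages data.table (version 1.17.8), statmod 1.5.0 and jsonlite 2.0.0 and random seed 11, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.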

Results

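Diploid yeast placed in sporulation medium copy their DNA, recombine their chromosomes and, if the transcription factor Ndt80 is absent, stop before the meiotic divisions. The series followed mRNA after NDT80 was switched on in such blocked cells, from 20 to 240 minutes, in 22 labelled time points on 24 arrays. Every time point had 1 array except 132 and 172 minutes, which had 2. Each array compared the RNA of a time point (Cy3) with RNA from the block (Cy5). On the 23 arrays used, the median Cy3 signal ranged from 463 to 3069 and the median Cy5 signal from 913 to 3422, in scanner units. Between 82.9% and 97.1% of spots were well above background in Cy3, and between 90.8% and 97.5% in Cy5. The 2 arrays of 132 minutes had a Pearson r of 0.891 across the 6118 genes tested, and 1179 genes (19.3%) differed between them by more than 1 on the log2 scale. For 172 minutes these values were 0.918 and 662 genes (10.8%). Genes are not independent replicates, so these r values describe the arrays only. The median residual SD of a gene around its fitted time course was 0.286.

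NDT80 (YHR124W, probe on chromosome 8 at 358377 to 358436, sacCer1) was above the block on every array. Its log2 ratio was 5.14 at 20 minutes, 6.50 at 40, 6.65 at 76 and 5.04 at 240 minutes. Over 20 to 60 minutes the mean of 3 time points was 5.89 ± 0.21 (limma adjusted p = 5.7e-13), with single values between 5.14 and 6.50. Here and below, ± gives limma's moderated SE. It comes from the residual spread over all 6 windows, not from the compared time points alone. From 68 to 92 to 132 to 156 minutes the difference was -0.98 ± 0.26 (adjusted p = 0.00476), which is under the fold minimum. It depends on the 132-minute repeat, whose 6.75 was the highest value of the series and was averaged with 5.50 on the first array. At 140, 148 and 156 minutes NDT80 stood at 5.54, 5.24 and 5.12.

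The first comparison asked how the cells at 20 to 60 minutes differed from the block. The strongest rises other than NDT80 were in genes of galactose use and of spore formation. GAL7, which encodes a galactose-processing enzyme (YBR018C, chromosome 2, 274491 to 274550), rose by 7.52 ± 0.30 (adjusted p = 1.91e-12) and GAL2, the galactose permease, by 6.15 ± 0.29 (2.24e-11). Among sporulation genes, SPS2 rose by 5.01 ± 0.44 (1.09e-07), IRC18 by 4.98 ± 0.56 (1.30e-06), RRT12 by 4.61 ± 0.54 (1.93e-06) and SPS4 by 4.44 ± 0.49 (1.12e-06). The polo kinase CDC5, which acts at exit from pachytene, rose by 4.14 ± 0.49 (2.49e-06), and CLB1, an M-phase cyclin (YGR108W, chromosome 7, 704828 to 704887), by 3.92 ± 0.53 (9.60e-06). Of the genes named by the rule, the largest falls were those of DAL5, the allantoate permease, at -4.22 ± 0.21 (4.19e-11), and MEP2, an ammonium permease, at -3.87 ± 0.46 (2.63e-06).

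Of the 36 measured genes of the prospore membrane and sporulation structure list, 28 rose, 0 fell and 8 did not pass (29 rose adjusted over the list alone), with a median of 2.68. YSW1, at 4.08 ± 0.40, was among them. The fry adjusted p was 3.30e-05, against an adjusted p = 0.419 with an estimated correlation. In the spore wall list 22 of 30 rose and 0 fell, also adjusted over the list alone, with a median of 2.93 (fry adjusted p = 1.85e-05, adjusted p = 0.419 with an estimated correlation). Members shared with the previous list include SPS2 and IRC18, and SPR2, a spore wall gene, rose by 4.41 ± 0.62. Of the 16 measured genes of the anaphase-promoting complex list, 10 rose and 0 fell (11 adjusted over the list alone) (fry adjusted p = 3.54e-04, adjusted p = 0.419 with an estimated correlation). They were led by the activator CDC20 at 3.35 ± 0.44, then APC1 at 2.09 ± 0.40 and CDC16 at 2.07 ± 0.32. M-phase cyclins and division regulators rose in 10 of 20 cases, also adjusted over the list alone, with 0 falls (fry adjusted p = 1.35e-04, adjusted p = 0.419 with an estimated correlation). Spindle pole body genes rose in 6 of 17 cases, also adjusted over the list alone (fry adjusted p = 1.85e-05, adjusted p = 0.419 with an estimated correlation). BBP1 at 2.86 ± 0.32, CNM67 at 2.64 ± 0.31 and SPC42 at 2.46 ± 0.40 were among these. The 12 Gal4-responsive genes included 9 rises and 0 falls, also adjusted over the list alone, with GAL1 at 3.91 ± 0.38 (fry adjusted p = 2.16e-09, adjusted p = 0.385 with an estimated correlation). The strain's construct is not in the labels, and strains induced with estradiol commonly carry an estradiol-activated form of Gal4 that drives a GAL promoter.

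Ribosomal protein genes were low from the start: 125 of 137 fell and 0 rose, also adjusted over the list alone, with a median of -2.21 and RPL24A at -3.56 ± 0.36 (fry adjusted p = 2.66e-06, adjusted p = 0.419 with an estimated correlation). Of the 10 genes of the histone list, which also holds HTZ1 and HHO1, 7 fell and 1 rose, also adjusted over the list alone. HTA2 was at -2.53 ± 0.20 and HTB2 at -2.34 ± 0.17 (fry adjusted p = 9.65e-08, adjusted p = 0.385 with an estimated correlation). The stress and storage carbohydrate list had 9 rises and 1 fall among 32, also adjusted over the list alone (fry adjusted p = 6.49e-04, adjusted p = 0.508 with an estimated correlation). Its risers included SGA1, a sporulation glucoamylase, at 3.16 ± 0.40, the chaperone SSA3 at 2.97 ± 0.31 and HSP12 at 2.36 ± 0.31. Autophagy genes rose in 4 of 24 cases, with ATG3 at 1.49 ± 0.26 (fry adjusted p = 2.66e-06, adjusted p = 0.385 with an estimated correlation). The smaller shifts that passed with fry were the mitotic exit list (4 rose and 1 fell of 21, adjusted p = 0.00177, and 0.524 with an estimated correlation) and the kinetochore list (2 rose and 1 fell of 37, adjusted p = 0.00858, and 0.655 with an estimated correlation). Monopolin and cohesion also passed (2 rose and 1 fell of 13, adjusted p = 0.00385, and 0.691 with an estimated correlation), as did mating genes (2 rose of 26, adjusted p = 0.0235, and 0.717 with an estimated correlation). In the monopolin list the risers were MAM1, which joins sister kinetochores, at 3.40 ± 0.29, and the cohesin protector SGO1 at 2.64 ± 0.32. Counts of the autophagy list and of these 4 lists were the same adjusted over the list alone. The median of the recombination list went from 0.75 at 20 minutes to 0.06 at 40 and -0.35 at 60 minutes. Averaged over the window, this list did not shift (4 rose and 2 fell of 40, fry adjusted p = 0.575), although IME1, the early inducer of meiosis, fell by 1.92 ± 0.23 (3.29e-06). Nor did ribosome biogenesis (3 rose and 1 fell of 48, adjusted p = 0.876), glyoxylate (2 and 3 of 20, 0.0728), respiration (2 and 3 of 34, 0.353), proteasome (1 and 0 of 33, 0.0815) or mitotic G1 genes (1 and 1 of 30, 0.949). Of these, camera with the preset correlation passed the proteasome list (adjusted p = 0.0481).

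In all, 485 genes were higher and 492 lower than in the block among the 6118 tested (limma, adjusted p under 0.05 and at least 2-fold). All 3 time points lay on 1 slide with 1 dye orientation, so slide and dye effects cannot be told apart from this difference. The counts became 745 and 866 with the Feature Extraction log ratio and 1092 and 1055 with between-array scaling, and 283 genes were higher when only these 3 time points were fitted.

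**Figure D1:**
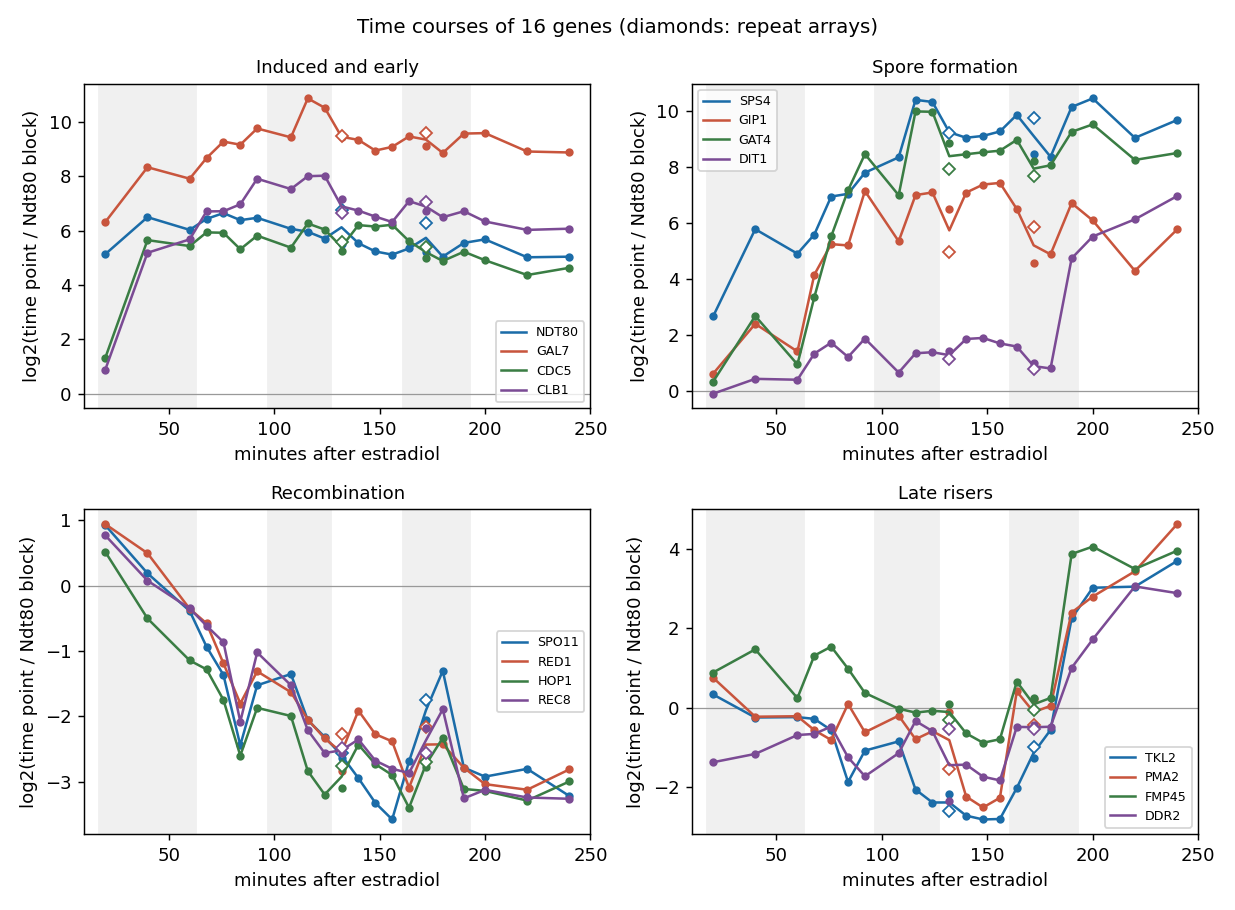
Log2 ratio of time point over block (vertical axes) against minutes after induction (horizontal axes) for 16 genes in 4 panels; points are arrays, diamonds the repeat arrays at 132 and 172 minutes, lines join time-point means, grey bands mark alternate windows and the 100-minute array is left out. NDT80 stayed between 5.02 and 6.75, SPO11, RED1, HOP1 and REC8 declined, and DIT1 went from 0.80 at 180 minutes to 4.73 at 190 minutes.

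Between 20 to 60 and 68 to 92 minutes more genes rose than fell. Lists of spore formation and of the meiotic divisions were among those that rose, while 22 of 40 genes of chromosome pairing and recombination fell. GAT4, a GATA-type transcription factor gene, rose by 4.80 ± 0.90 (adjusted p = 0.00319), LOH1 by 4.07 ± 0.73 (0.00304), GIP1, which targets a phosphatase to the forming spore, by 3.96 ± 0.68 (0.00256), the ubiquitin-conjugating enzyme gene UBC11 by 3.86 ± 0.71 (0.00317) and SPO19 by 3.81 ± 0.58 (0.00182). Further large rises were IRC10 at 3.63 ± 0.72, SPO77 at 3.62 ± 0.78, SPS1, a sporulation kinase, at 3.59 ± 0.61 and SMA2, needed for prospore membrane growth, at 3.53 ± 0.90. Against these, SPO11, whose product makes the meiotic DNA breaks, fell by 1.81 ± 0.39 (0.00485), and the chromosome axis gene RED1 fell by 1.58 ± 0.29 (0.00319). The cell surface flocculin FLO11 fell by 1.96 ± 0.45 (0.00636).

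Of the 40 measured recombination and synapsis genes, 22 fell and 0 rose, also adjusted over the list alone, with a median of -1.09. ECM11 at -1.55 ± 0.30 and SPO22 at -1.54 ± 0.34, both of the synaptonemal complex pathway, were among them (fry adjusted p = 0.00419, adjusted p = 0.419 with an estimated correlation). Anaphase-promoting complex genes rose in 13 of 16 cases (14 adjusted over the list alone), with CDC26 at 2.83 ± 0.61, APC1 at 2.42 ± 0.53 and CDC23 at 2.29 ± 0.43 (fry adjusted p = 0.00131, adjusted p = 0.419 with an estimated correlation). M-phase regulators rose in 11 of 20 (12 adjusted over the list alone), with the cyclins CLB6 at 3.20 ± 0.53 and CLB1 at 3.16 ± 0.70 (fry adjusted p = 0.00497, adjusted p = 0.524 with an estimated correlation). The mitotic exit list had 8 rises among 21 (9 adjusted over the list alone), including the transcription factor SWI5 at 2.81 ± 0.34 (fry adjusted p = 4.26e-04, adjusted p = 0.419 with an estimated correlation). In the prospore list 29 of 36 rose and 1 fell (31 and 1 adjusted over the list alone), and in the spore wall list 22 of 30 rose and 1, SHC1, fell (23 and 1 adjusted over the list alone). Their fry adjusted p values were 0.00128 and 0.00177, each with an adjusted p = 0.419 with an estimated correlation. These list medians depended on the normalization and the source of the values, although none reversed. The prospore median of 2.47 went as low as 0.43 and the spore wall median of 2.18 as low as 0.17. M-phase regulators went from 1.43 to as low as 0.25, the anaphase-promoting complex from 1.86 to 0.71 and mitotic exit from 0.78 to 0.28. The recombination median stayed between -1.31 and -1.03. Of the list marking cells outside meiosis, mitotic G1 and bud growth, 14 of 30 rose and 0 fell, also adjusted over the list alone (fry adjusted p = 3.37e-04, adjusted p = 0.419 with an estimated correlation). Its leaders HOF1 at 2.96 ± 0.48, SWI5 and RAX2 at 2.28 ± 0.43 act in cytokinesis, late M-phase transcription and bud site choice. Mating and haploid genes had 8 rises and 1 fall among 26, also adjusted over the list alone (fry adjusted p = 0.00229, adjusted p = 0.524 with an estimated correlation). They were led by the G protein subunit genes STE18 at 2.50 ± 0.46 and STE4 at 2.05 ± 0.46.

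Kinetochore and spindle genes rose in 5 of 37 cases (6 adjusted over the list alone), with the spindle midzone gene ASE1 at 2.31 ± 0.31 (fry adjusted p = 0.0210, adjusted p = 0.784 with an estimated correlation). Spindle pole body genes rose in 6 of 17 (fry adjusted p = 0.00434, adjusted p = 0.598 with an estimated correlation), and their median of 0.61 became -0.08 with between-array scaling. Gal4-responsive genes rose in 5 of 12 (fry adjusted p = 0.00342, adjusted p = 0.508 with an estimated correlation), with GAL10 at 2.86 ± 0.74. Their median of 0.44 became -0.93 with between-array scaling, under which GAL7 turned from 1.70 to -3.56. Autophagy genes rose in 4 of 24 (fry adjusted p = 0.00803, adjusted p = 0.722 with an estimated correlation), but their median of 0.20 went as low as -0.16 under another scaling. Proteasome genes shifted down, with 1 fall among 33 and a median of -0.57 (fry adjusted p = 0.00763, adjusted p = 0.419 with an estimated correlation). The counts of the last 4 lists were the same adjusted over the list alone. No shift was found for monopolin and cohesion (2 rose, 4 fell, fry adjusted p = 0.0992), stress (4 and 2, 0.990) or histones (0 and 0, 0.575). Nor was there one for ribosome biogenesis (3 and 0, 0.641), glyoxylate (0 and 0, 0.575), respiration (1 and 1, 0.185) or ribosomal protein genes (3 and 0, 0.427). The respiration median was -0.51, and camera with the preset correlation passed that list (adjusted p = 3.85e-04).

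Altogether 636 genes were higher and 81 lower (88.7% higher), while 70.9% were higher with the Feature Extraction log ratio and 75.5% with between-array scaling. With slide as a fixed block 0 genes passed in either direction (limma, 276 higher and 14 lower at an unadjusted p under 0.05), and no list passed (lowest fry adjusted p 0.140). The 636 and 81 genes, chosen with these same arrays, had medians of 1.11 and -0.80 under the block, in place of 1.51 and -1.21, and their median SE was 0.52 in place of 0.36. As a random block the slide gave counts of 242 and 11. Within the slide that holds 20, 40, 60 and 68 minutes, the list medians at 68 minutes against the earlier 3 were 1.65 for the prospore list, 1.39 for the anaphase-promoting complex and -0.65 for recombination. The counts were 200 and 4 without 20 minutes, 803 and 212 without 60 minutes, and 397 and 38 with the 100-minute array included. When only the 7 time points of these windows were fitted, 0 genes passed (limma, 653 higher and 87 lower unadjusted), with the same folds by construction and fewer residual degrees of freedom. The median SE of the 636 and 81 genes was then 0.43 in place of 0.36, while that of all genes was 0.22 in place of 0.24. The called genes thus varied more within these windows than the spread over all windows gave.

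From 68 to 92 to 132 to 156 minutes, 11 of 20 genes of the glyoxylate and gluconeogenesis list, 18 of 34 respiration genes and 19 of 40 recombination genes fell. The respiration and recombination shifts did not pass without 140, 148 and 156 minutes (fry adjusted p = 0.260 and 0.125). Their medians were then -0.48 and -0.91, in place of -1.05 and -0.93. That window was then the mean of the first 132-minute array, with a respiration median of -2.33, and its repeat, with -0.50. On the mean of the 3 arrays at 140, 148 and 156 minutes, 117 genes were at least 4-fold lower than on the mean of the first arrays of 132 and 172 minutes. By the same rule 22 genes were higher. Of the 645 lower genes, 106 were among the 117. Values with 164 to 190 minutes in place of 132 to 156 minutes are therefore given after "against", a choice made after the fall was seen. ACS1, acetyl-CoA synthetase, fell by 4.47 ± 0.50 (adjusted p = 3.61e-05) against -2.65 at 164 to 190 minutes (5.98e-04). The carnitine shuttle genes CRC1, CAT2 and YAT1 fell by 2.53 ± 0.41, by 2.29 ± 0.27 and by 2.09 ± 0.30, against -2.50, -2.06 and -2.95. PDH1, of propionate breakdown, fell by 3.08 ± 0.42 (7.11e-05) against -2.34 (3.79e-04). Genes with the largest rises included PSF3 of the GINS replication complex at 2.60 ± 0.32 (4.88e-05) against 3.01 (7.60e-06) and MPD1, a protein disulfide isomerase of the endoplasmic reticulum, at 3.17 ± 0.47 (1.12e-04) against 2.95 (1.60e-04). GDS1 stood at 2.66 ± 0.39 (1.02e-04) against 3.04 (2.58e-05) and YET2 at 2.67 ± 0.38 (8.08e-05) against 2.80 (4.21e-05). Other falls were not found past the thresholds at 164 to 190 minutes: ATG22, a vacuolar transporter, at -3.77 ± 0.61 against -1.21 (0.137), and PHB1, prohibitin, at -3.68 ± 0.55 against -1.11 (0.129). The largest rise, SRD1 at 3.59 ± 0.92, was 1.85 there (0.129).

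Of the 20 glyoxylate and gluconeogenesis genes, 11 fell and 1 rose, with a median of -1.33, or -1.76 with 164 to 190 minutes (fry adjusted p = 3.06e-05, adjusted p = 0.419 with an estimated correlation). Of the 34 respiration genes, 18 fell and 0 rose, with medians of -1.05 against -0.97 (fry adjusted p = 0.00177, adjusted p = 0.524 with an estimated correlation). The ATP synthase genes ATP2 and ATP1 fell by 3.47 ± 0.55 and by 2.33 ± 0.33, against -2.01 and -1.69. Recombination genes fell further, 19 of 40 with 0 rises and medians of -0.93 against -0.70 (fry adjusted p = 0.00311, adjusted p = 0.524 with an estimated correlation). Among them were the checkpoint kinase MEK1 at -1.85 ± 0.35 against -1.95 and the synaptonemal complex gene ZIP1 at -1.71 ± 0.29 against -1.57. Monopolin and cohesion genes had 3 falls among 13 and medians of -0.45 against -0.49, including the meiotic cohesin REC8 at -1.44 ± 0.32 against -1.45 (fry adjusted p = 0.00177, adjusted p = 0.538 with an estimated correlation). In the proteasome list 9 of 33 fell, with RPT4 at -1.52 ± 0.22 against -1.65 (fry adjusted p = 0.00970, adjusted p = 0.653 with an estimated correlation). The proteasome median was -0.43 against -0.92, and the first became 0.01 with median centring in place of loess. Gal4-responsive genes had 4 falls among 12 and medians of -0.34 against -0.70, with PGM2, phosphoglucomutase, at -1.71 ± 0.27 against -2.53 (fry adjusted p = 0.0278, adjusted p = 0.745 with an estimated correlation). Autophagy genes shifted down, with medians of -0.39 against -0.25 (fry adjusted p = 0.00803, adjusted p = 0.653 with an estimated correlation), although 3 rose and 2 fell among 24. ATG14 was at 2.49 ± 0.35 against 1.73, and ATG1 at -1.15 against 0.52, where it did not pass (adjusted p = 0.228). Mitotic G1 and bud growth genes rose in 10 of 30 cases with 1 fall, including EGT2, of cell separation, at 1.93 ± 0.35 against 2.51 (fry adjusted p = 0.00402, adjusted p = 0.524 with an estimated correlation). Their median was 0.66 against 0.29, and the first became -0.01 with between-array scaling. Mating genes rose in 5 of 26 cases with 1 fall, led by STE18 at 2.12 ± 0.43 against 1.32 (fry adjusted p = 5.49e-04, adjusted p = 0.419 with an estimated correlation). Their median was 0.48 against 0.07, and 0.16 without 140, 148 and 156 minutes (fry adjusted p = 0.215). On those 3 arrays the list stood at 1.36, 1.48 and 1.51, with 0.75 on the first array of 132 minutes and 0.74 at 164 minutes. These 9 lists had the same counts adjusted over the list alone. Lists without a shift were the M-phase regulators (1 rose, 1 fell, fry adjusted p = 0.604), anaphase-promoting complex (5 and 3, 0.575), kinetochore (5 and 0, 0.431), spindle pole body (2 and 2, 0.833) and mitotic exit (2 and 0, 0.949). The same held for prospore (3 and 2, 0.411), spore wall (3 and 2, 0.764), stress (2 and 6, 0.132), histones (1 and 1, 0.990), ribosome biogenesis (2 and 2, 0.730) and ribosomal protein genes (2 and 13, 0.680).

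The totals were 594 genes higher and 645 lower. Of these, 248 and 251 also passed with 164 to 190 minutes in place of the later window. With 132 minutes as the only time point of its window, 0 genes passed (limma, 94 higher and 161 lower at an unadjusted p under 0.05). The 594 and 645 genes, chosen with these arrays among others, then had medians of 0.69 and -0.65 in place of 1.36 and -1.37, and their median SE was 0.39 in place of 0.29. Of the 9 list shifts, 2 held (glyoxylate, fry adjusted p = 0.00403, and monopolin and cohesion, 0.0418). No slide held time points of both windows, and with slide as a random block 340 genes were higher and 374 lower. Between-array scaling gave 223 and 310.

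**Figure D2:**
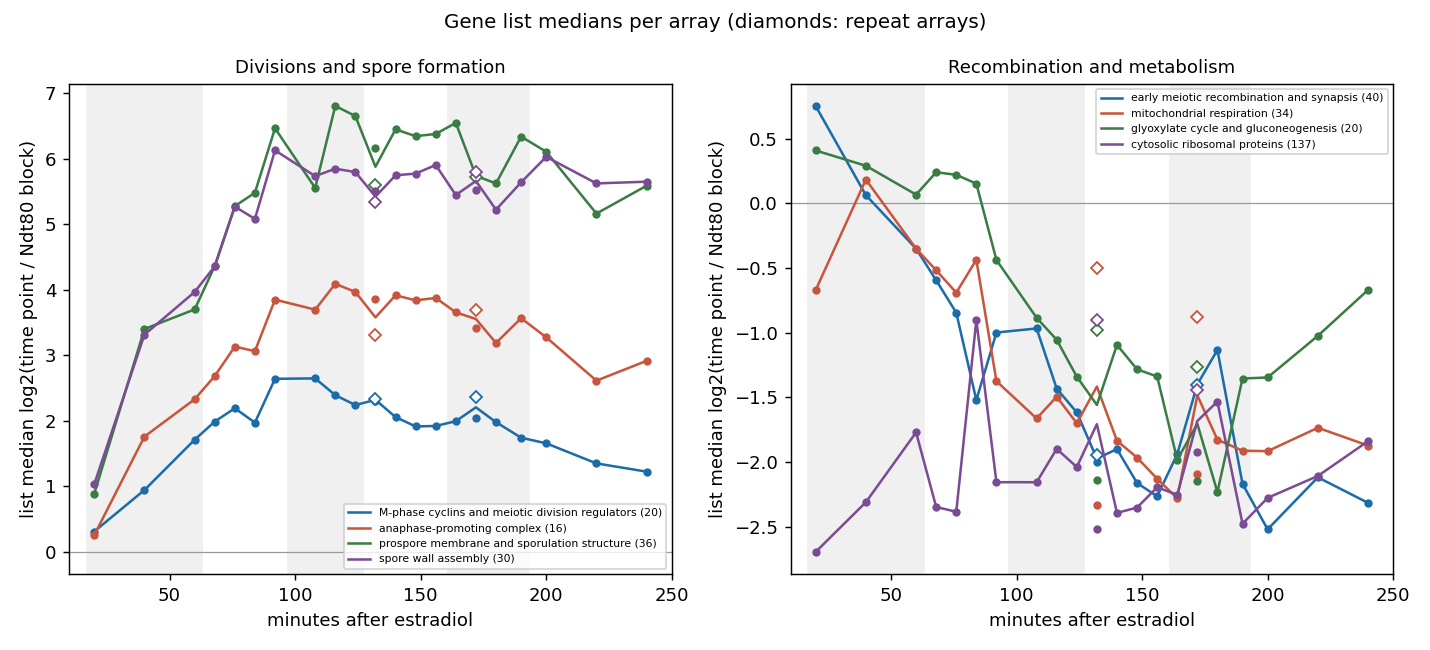
Median log2 ratio of time point over block (vertical axis) against minutes after induction (horizontal axis) for 8 of the fixed gene lists in 2 panels, 1 point per array, with diamonds for the repeat arrays and lines through time-point means. The prospore list was highest at 116 minutes (6.81), the recombination list lowest at 200 minutes (-2.52) and the ribosomal protein list lowest at 20 minutes (-2.70).

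Between 132 to 156 and 200 to 240 minutes, 11 of the 32 genes of the stress and storage carbohydrate list rose and 2 fell. TKL2, a transketolase, rose by 5.92 ± 0.66 (adjusted p = 9.02e-06), PMA2, a plasma membrane proton pump, by 5.56 ± 0.53 (4.17e-06), RTN2, of the endoplasmic reticulum, by 5.19 ± 0.68 (2.16e-05) and GIC1, an effector of Cdc42, by 4.59 ± 0.51 (9.02e-06). DIT1, which makes the dityrosine precursor of the spore wall (YDR403W, chromosome 4, 1276120 to 1276179), rose by 4.52 ± 0.63 (3.02e-05). Measured from 164 to 190 minutes, these rises were 3.61 for TKL2, 2.93 for PMA2, 2.20 for RTN2, 2.15 for GIC1 and 4.20 for DIT1, with adjusted p from 0.00141 to 0.0393. That window is not free of the late rises. Its last array, at 190 minutes, had DIT1 at 4.73 and TKL2 at 2.25, against 0.80 and -0.55 at 180 minutes. The stress gene DDR2 rose by 4.16 ± 0.38 (2.66 from 164 to 190 minutes, adjusted p = 0.00130) and FMP45, a membrane protein gene, by 4.43 ± 0.61 (2.61, 0.0117). In contrast HAC1, the transcription factor of the unfolded protein response, was 4.05 ± 0.85 higher but 0.14 (0.932) from 164 to 190 minutes, and UGP1, which makes UDP-glucose, was 3.88 ± 0.72 higher but -0.18 (0.893). Falls included the copper transporter CTR3 at -2.65 ± 0.67 (-1.74 from 164 to 190 minutes, 0.0889), CDC26 at -2.37 ± 0.61 (-0.61, 0.535), the malate dehydrogenase MDH2 at -2.26 ± 0.38 (-0.72, 0.211), the cyclin CLB6 at -2.10 ± 0.53 (-0.75, 0.363) and TWF1, twinfilin, at -2.08 ± 0.28 (-1.14, 0.0158).

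The stress and storage carbohydrate list had a median of 0.70, or 0.39 from 164 to 190 minutes. Within that earlier window the list stood at 0.13 at 180 minutes and already at 0.85 at 190 minutes. The fry adjusted p was 0.00311 (adjusted p = 0.524 with an estimated correlation), but 0.195 without 140, 148 and 156 minutes and 0.140 with slide as a fixed block. Glycogen synthase GSY2 rose by 3.31 ± 0.47, the stress gene GRE1 by 3.01 ± 0.35 and the glycogen branching gene GLC3 by 2.58 ± 0.32, or by 1.90, 1.94 and 1.16 from 164 to 190 minutes. Ribosome biogenesis genes rose in 15 of 48 cases with 2 falls, with NSR1 at 3.20 ± 0.49, IMP3 at 2.54 ± 0.34, MAK16 at 2.34 ± 0.36 and RPF2 at 2.21 ± 0.30 (fry adjusted p = 0.0195, adjusted p = 0.653 with an estimated correlation). From 164 to 190 minutes these 4 genes were at 1.96, 1.53, 1.49 and 1.68, and the list median was 0.45 in place of 0.47. Downward shifts were found for M-phase regulators (3 of 20 fell, fry adjusted p = 0.0400, adjusted p = 0.761 with an estimated correlation), with the kinase CDC28 at -1.61 ± 0.23 (-0.84 from 164 to 190 minutes). Kinetochore genes shifted down as well (7 of 37 fell and 2 rose, 0.00638, adjusted p = 0.713 with an estimated correlation), with the kinesin CIN8 at -1.91 ± 0.41 (-0.54, 0.402). The mitotic exit list had 3 falls and 2 rises among 21 (0.0133, adjusted p = 0.717 with an estimated correlation), with the kinase CDC15 at -1.78 ± 0.22 (-0.79) and FOB1, of the ribosomal DNA, at 2.17 ± 0.32 (1.25). Histone genes fell in 4 of 10 cases (0.00733, adjusted p = 0.717 with an estimated correlation) and proteasome genes in 6 of 33 (0.00861, adjusted p = 0.691 with an estimated correlation), the latter including PRE1 at -1.84 ± 0.23 (-0.76). Mating genes had 8 falls and 1 rise among 26 (8.54e-04, adjusted p = 0.524 with an estimated correlation), with the pheromone receptor STE3 at -1.58 ± 0.29 (-0.84, 0.0590). Without 140, 148 and 156 minutes, where the mating list was highest, 0 of its genes fell and 1 rose (fry adjusted p = 0.182 for the list). Monopolin and cohesion genes had 2 falls among 13 (9.66e-04, adjusted p = 0.524 with an estimated correlation), 1 adjusted over the list alone, and the other 8 of these lists had the same counts adjusted over the list alone. From 164 to 190 minutes the medians were smaller for histones (-0.12 in place of -0.56), the proteasome (-0.18 in place of -0.65), mating genes (-0.20 in place of -0.50) and monopolin and cohesion (-0.37 in place of -0.57). They were -0.49 in place of -0.50 for M-phase regulators, -0.27 in place of -0.34 for kinetochore genes and -0.45 in place of -0.55 for the mitotic exit list. No shift was found for Gal4-responsive genes (0 rose, 2 fell, fry adjusted p = 0.240), anaphase-promoting complex (1 and 4, 0.134), spindle pole body (2 and 3, 0.185), or recombination (1 and 6, 0.167). Nor was there one for prospore (1 and 6, 0.391), spore wall (3 and 4, 0.949), glyoxylate (5 and 4, 0.353), respiration (2 and 3, 0.949), autophagy (3 and 1, 0.990), mitotic G1 (4 and 8, 0.0868) or ribosomal protein genes (13 and 7, 0.789).

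This comparison gave 747 genes higher and 713 lower (51.2% higher, against 69.2% with between-array scaling, where the counts were 416 and 185). With 164 to 190 minutes as the earlier window 213 genes were higher and 20 lower, of which 198 and 14 were among the 747 and 713. The 190-minute array of that window had an r of 0.987 with 200 minutes and 0.925 with 180 minutes. This choice therefore leaves out changes that had taken place by 190 minutes in part. Without 140, 148 and 156 minutes the counts were 377 and 151 and 1 list shift held (monopolin and cohesion, fry adjusted p = 0.0380). With slide as a fixed block 562 and 524 genes passed, and 2 of the 9 list shifts held (monopolin and cohesion, fry adjusted p = 0.0258, and histones, 0.0439). That fit links the windows only through the 132-minute repeat, and through 140, 148 and 156 minutes by way of 164 to 190 minutes. Within the slide that holds 220 and 240 minutes and the 132-minute repeat, the list medians were 0.17 for stress and 0.79 for ribosome biogenesis. On the fitted curves of 230 genes that repeat was placed at 96 minutes, not at its label.

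Over the whole course, 4128 of 6118 genes (67.5%) changed (limma spline, adjusted p under 0.05 and a fitted range of at least 1). The largest fitted ranges were those of GAT4 (9.36), CTR3 (8.48), the hexose transporter gene HXT10 (7.98), the chitinase-like gene CTS2 (7.95), DIT1 (7.91), UBC11 (7.58), SGA1 (7.34), RRT12 (7.33), SPO19 (7.33) and SMA2 (7.27). Peaks are those of the fitted curves and can differ from the highest array. Peaks of the changing genes fell mostly in the first window (1152 genes), at 132 to 156 minutes (879) and in the last window (996). There were 436 at 68 to 92, 469 at 100 to 124 and 196 at 164 to 190 minutes. By list, all 16 anaphase-promoting complex genes changed, with a median peak at 124 minutes, as did 34 of 36 prospore genes and 29 of 30 spore wall genes with the same median peak. M-phase regulators (18 of 20) had a median peak at 92 minutes and mitotic exit genes (20 of 21) at 120 minutes. Recombination genes (39 of 40) and proteasome genes (32 of 33) had their median peak at the first time point, 20 minutes. Respiration genes (29 of 34) had a median fitted peak at 20 minutes, but their list median was -0.67 there and highest at 40 minutes (0.18). Glyoxylate genes (19 of 20) had a median fitted peak at 40 minutes, but their list median was highest at 20 minutes (0.41). Ribosome biogenesis genes (38 of 48) peaked at a median of 240 minutes. Of the 32 stress genes 26 changed, with a median fitted peak at 140 minutes. Their list median was lowest at 156 minutes (-0.45) and highest at 190 minutes (0.85). Of the 137 ribosomal protein genes, 49 changed. With slide as a fixed block 2661 genes passed.

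**Figure D3:**
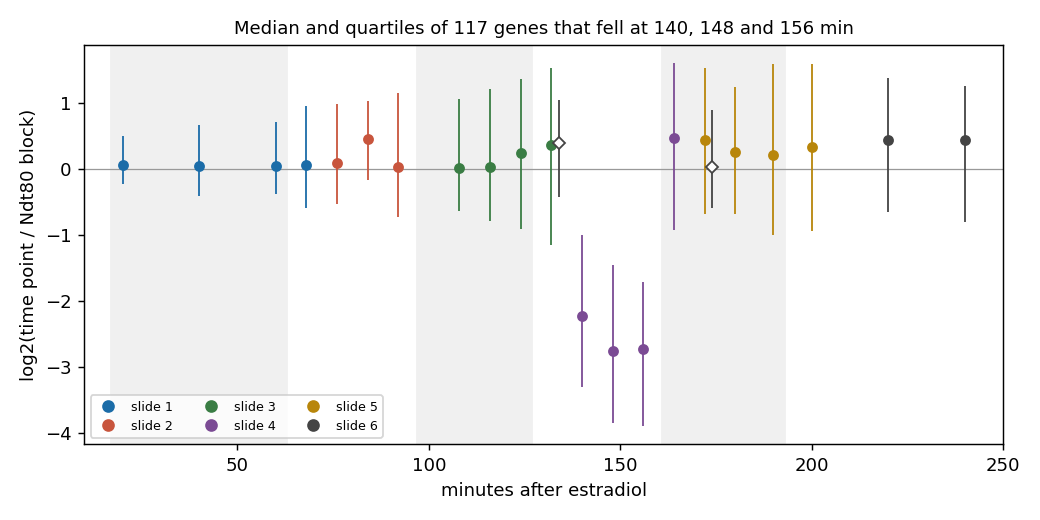
Log2 ratio of time point over block (vertical axis) against minutes (horizontal axis) for 117 genes. These were at least 4-fold lower on the mean of 140, 148 and 156 minutes than on the mean of the first arrays of 132 and 172 minutes. Points are medians with quartiles on each array, coloured by slide. Open diamonds are the repeat arrays, drawn 2 minutes to the right of their label. The median change was -2.20 from 132 to 140 minutes and 2.87 from 156 to 164 minutes.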

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

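No test was run on the result below, so none was chosen after it was seen. The 100-minute array, which the submitters marked as failing quality control, still carried the induced gene. NDT80 stood at a log2 ratio of 4.11 there, a signal above the block on an array left out of the comparisons except in the alternative that includes it. On all other arrays NDT80 lay between 5.02 and 6.75. The median Cy3 signal of the array was 60.3 scanner units. Of its spots, 42.4% were well above background in Cy3 and 92.3% in Cy5. Across genes, which are not independent replicates, its r was 0.700 with the 92-minute array and 0.707 with the 108-minute array. Those 2 arrays had an r of 0.965 with each other.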

How the results depend on the processing

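The settings that left out 140, 148 and 156 minutes, left out 84 minutes with both repeats, or used 164 to 190 in place of 132 to 156 minutes were chosen after the data were seen. Named genes had 13790 values under the alternatives. Of these, 12803 kept their direction and passed again, 950 kept their direction without passing and 37 reversed. Many of these values come from fits that left out 1 time point, often outside the compared windows. Others keep the log ratios by construction, and the genes were named for large changes on the same arrays. The share that passed again is therefore no measure of stability by itself. Counts under the planned settings, apart from leaving out time points, ranged from 283 to 1358 higher and 434 to 1353 lower against the block. For 68 to 92 against 20 to 60 minutes they ranged from 0 to 1038 and from 0 to 433. For 132 to 156 against 68 to 92 they ranged from 223 to 1426 and from 310 to 1528. For 200 to 240 against 132 to 156 they ranged from 416 to 1313 and from 185 to 1667, and over time from 2661 to 4969. Only 5078 genes were well above background in both channels on every array used, and with these alone the counts of the comparisons and of the time course stayed within 1.5 times. Quantile normalization of brightness leaves log ratios as they are, so it tests nothing here. Leaving out 84 minutes with both repeats kept these counts within 1.5 times. Except where the construction of an alternative is named, the cause was not tested. No paired analysis was possible because nothing in the labels pairs an array of one window with an array of another.

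Leaving out 1 time point at a time gave 390 to 644 higher and 441 to 554 lower genes against the block. The ranges were 200 to 803 and 4 to 212 for 68 to 92 against 20 to 60, and 494 to 809 and 513 to 869 for 132 to 156 against 68 to 92. They were 653 to 886 and 570 to 873 for 200 to 240 against 132 to 156, and 4001 to 4257 over time. For 68 to 92 against 20 to 60 the counts were 200 and 4 without 20 minutes and 803 and 212 without 60 minutes. Lower genes there were 132 without 68 and 51 without 92 minutes.

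With the Feature Extraction log ratio, 745 genes were higher and 866 lower than the block, and 188 were lower at 68 to 92. With no minimum fold, which by construction admits smaller changes, the 4 comparisons had 1358 and 1353, 1038 and 433, 1426 and 1528, and 1313 and 1667 genes. With the 100-minute array included, 68 to 92 against 20 to 60 had 397 and 38. Between-array scaling, which widens arrays with a narrow spread of ratios, gave 1092 and 1055 against the block and 188 lower at 68 to 92. It gave 223 and 310 at 132 to 156, and 416 and 185 at 200 to 240. Under it, genes reversed at 68 to 92 were GAL7 -3.56, GAL1 -1.08, BBP1 -0.099, SGO1 -0.44, SPS2 -0.22, SSA4 -0.066, COX5B -0.079 and ATG4 -0.080. At 132 to 156 they were CDC26 -0.33, CDC23 -0.58, SPS4 -0.81, OSW7 -0.24, SPO19 -1.07, SPR1 -0.89 and SGA1 -1.23.

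The slide as a fixed block could not be fitted against the block or for 132 to 156 against 68 to 92 minutes, where no slide links the windows. It left 0 and 0 genes for 68 to 92 against 20 to 60 (limma, 276 and 14 at an unadjusted p under 0.05). The 636 and 81 genes, chosen with the same arrays, had medians of 1.11 and -0.80 in place of 1.51 and -1.21, and their median SE was 0.52 in place of 0.36. It left 2661 genes over time, and ATP2 was at -0.40 for 200 to 240. As a random block (consensus correlation 0.287) the slide gave 242 and 11 for 68 to 92, and 340 and 374 for 132 to 156. Fitting only the compared windows, which leaves fewer residual degrees of freedom, gave 283 higher against the block. For 68 to 92 it gave 0 and 0 (limma, 653 and 87 at an unadjusted p under 0.05). The 636 and 81 genes then had a median SE of 0.43 in place of 0.36.

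Of 20 lists, fry passed 14, 13, 9 and 9 in the 4 comparisons in order. Camera with an estimated correlation passed 0 in each, and with the preset correlation 12, 10, 6 and 3. The slide as a fixed block left 0 for 68 to 92 and 2 for 200 to 240. Without 140, 148 and 156 minutes, 2 passed for 132 to 156 and 1 for 200 to 240.

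Without 140, 148 and 156 minutes, 0 and 0 genes passed for 132 to 156 (limma, 94 and 161 at an unadjusted p under 0.05). That window then held 1 time point, assumed to vary like the others. The 594 and 645 genes had medians of 0.69 and -0.65 in place of 1.36 and -1.37, and their median SE was 0.39 in place of 0.29. For 200 to 240 the counts were 377 and 151. Reversed for 132 to 156 were ATG1 0.16 and RPL15A 0.41. Reversed for 200 to 240 were SWM1 -1.01, MPS2 -0.59, ADY3 -0.38, ATP2 -0.72, ATG22 -0.64, RPS0B -0.12 and RPL15A -0.21. With 164 to 190 in place of 132 to 156 minutes, 384 genes were lower than at 68 to 92, and 213 were higher and 20 lower at 200 to 240. Reversed against 68 to 92 were CDC26 -0.30, DAD2 -0.083, NUD1 -0.35, ATG1 0.52 and HO -0.48. Reversed at 200 to 240 were UGP1 -0.18, SWM1 -0.66, DAD2 0.11, MPS2 -0.35, ADY3 -0.60, ATG22 -0.17 and ATG1 -0.36.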

Other observations

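The tests of the slide for the first 2 patterns, of probe brightness, of dye and brightness bias and of the reference RNA, and the choice of the genes and time steps in the first 2 paragraphs, came after the result was seen. The 7 genes given next, for the use of nitrogen sources such as allantoin and urea, were low from the first window on, and no list of such genes was tested. DAL4, DCG1, DAL7 and DAL3 stood at -3.26, -3.34, -3.46 and -3.61 at 20 to 60 minutes. At 200 to 240 minutes they stood at -2.76, -3.06, -3.24 and -2.78. The urea amidolyase gene DUR12 stood at -3.38 and -3.28 in these windows, the urea transporter gene DUR3 at -2.43 and -2.20 and the amino acid permease gene GAP1 at -2.05 and -1.95. For these 7 genes the adjusted p against the block ranged from 3.31e-09 to 5.80e-06 (limma). At 84 minutes DAL3 reached -0.07 and GAP1 -0.01, the highest values of the course for both. They rest on 1 array, where the ribosomal protein median also stood apart from its neighbours (given below). Among B-type cyclin genes, CLB3 was highest at 108 minutes (4.66), CLB4 and CLB5 at 92 (4.76 and 2.98), CLB1 at 124 (8.02) and CLB6 at 140 (6.17). CLB2, the main mitotic member of the family, was 0.36 at 20 to 60 minutes (limma adjusted p = 0.163) and 2.96 at 124 minutes.

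Between 180 and 190 minutes, on 2 arrays of the same slide, 80 genes rose by more than 4-fold and 6 fell by as much. Between 190 and 200 minutes 0 and 0 did so, and 0 and 2 between 172 and 180. At 220 to 240 minutes all 80 were still above their 180-minute value, 65 of them by at least 2-fold. Among the 80 were FMP45 (0.25 to 3.87), TKL2 (-0.55 to 2.25) and the hexose transporter gene HXT1 (0.61 to 3.81). The heat shock family gene HSP33 (0.65 to 4.05) and SPO75 (1.49 to 4.34) were also among them. Of the fixed lists, the prospore list held 3 of the 80 genes and the spore wall list 2. SPS100, a gene of late spore wall maturation, lay between -1.23 and -0.19 at all time points used. Other steps on a single slide were 129 up and 1 down from 20 to 40 minutes, 61 and 16 from 76 to 84, 4 and 46 from 84 to 92, 60 and 1 from 108 to 116, 2 and 15 from 124 to 132, and 152 and 16 from 156 to 164 minutes. The remaining steps on 1 slide had at most 9 up and at most 2 down. No test of these steps was run, and each end rests on 1 array.

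The first pattern is the fall of 117 genes at 140, 148 and 156 minutes, with medians of -2.30, -2.67 and -2.81 relative to the first arrays of 132 and 172 minutes. The genes were picked on the mean of the 3 arrays, on which 22 other genes rose by as much. A slide effect is argued against, since at 164 minutes, on the same slide, the median of the 117 genes was 0.038. So is the within-array normalization, as the median fall was -2.85 with arrays only centred. RNA preparation or labelling of these 3 samples stays open and cannot be told apart from a change in the cells, because the labels record no preparation batch; between repeat and first arrays the genes differed by -0.080 in median. A change in the cells between 132 and 164 minutes may also account for the fall but was not tested, and the fixed lists held few of the genes, such as 4 of 137 ribosomal protein genes and 2 of 24 autophagy genes.

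The second pattern is the shift of both repeat arrays from the first arrays of the same time points, at least 2-fold in the same direction for 425 genes (258 up, 167 down), with 23 of 34 respiration genes among those up. Probe brightness stays open, with a Spearman rho of -0.40 across genes between the shift and brightness when arrays were only centred, short of the 0.5 set for a brightness effect and beyond the 0.3 set against one. The signed median shift was 0.19 at 84 minutes, on another slide, and 0.19 at 220 and 240 minutes, on the slide of the repeats, so neither bore the shift in full. The respiration median was -1.74 and -1.87 at 220 and 240 minutes, near -1.92 at 200 minutes on another slide. On the repeats it was -0.50 and -0.88. This argues against an effect of the whole slide on respiration genes, while an effect on the repeat arrays alone stays open. Mislabelled time points remain a candidate explanation, since 230 genes placed the repeats at 96 and 100 minutes, 36 and 72 minutes from their labels, while the 21 first arrays were off by a median of 4 and at most 32 minutes; the 32 is the first array of 132 minutes, so the contrast holds for 172 minutes and hardly for 132. No biological explanation was tested, as the labels give none for 2 arrays of 1 time point.

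The third pattern is the low ribosomal protein RNA already at 20 minutes, with a median of -2.70 against -1.77 at 60 minutes. Single arrays departed from this level. The median was -0.90 at 84 minutes, between -2.39 at 76 and -2.16 at 92 minutes. On the 132-minute repeat it was -0.90, against -2.52 on the first array. A dye bias that follows brightness is argued against by 685 other genes of matched brightness, with a median of 0.015 (quartiles -0.43 and 0.48) at 20 to 60 minutes with arrays only centred, and within-array normalization by a ribosomal median of -2.26 on the same scale. A dye bias of single genes was not tested, as no dye was swapped. The block RNA itself stays open: a reference rich in these transcripts could give the same start, the median rose by 0.92 from 20 to 60 minutes, and no second block sample was measured. A fall in the cells within 20 minutes, the biological alternative, was not tested apart from this.

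In each of the 3 comparisons between windows, 1 of 35 splits of the time points, the real one, gave the most genes. With 35 splits the share cannot be lower than this. Neighbouring time points mostly shared a slide, and any drift along the course favours a split by time. The splits therefore cannot exclude slide or drift. The comparison with the block has no second group to split. The totals were 717 for 68 to 92 against 20 to 60 minutes (highest other 586), 1239 for 132 to 156 against 68 to 92 (957) and 1460 for 200 to 240 against 132 to 156 (1357). The split with 586 genes set 20, 40, 60 and 68 minutes against 76, 84 and 92, which are 2 slides. The slide as a fixed block left 0 and 0 (limma, 276 and 14 at an unadjusted p under 0.05). The split with 957 genes set 92, 140, 148 and 156 minutes against the rest, and without 140, 148 and 156 minutes 0 and 0 genes passed (limma, 94 and 161 at an unadjusted p under 0.05). The split with 1357 genes set 140, 148 and 156 minutes against the rest, the arrays of the first pattern, which points to a structure of these samples. With the slide as a fixed block 562 and 524 genes passed there, in a fit that still rests on these arrays. For the time course, 1 of 100 orders of the time points, the real one, gave 4128 genes, and the highest of the others 358. A random order of the time points is argued against, but a slide effect or drift that follows time is not.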
